A study of Mus musculus with 12 samples.

How the data were processed

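RNA sequencing counts of 12 mouse libraries, 3 in each of 4 groups, were compared. The groups, taken from the labels, were mouse embryonic fibroblasts 3 weeks after an empty vector (E), after Gata4, Hand2, Mef2c and Tbx5 (GHMT) and after these factors with Akt1 (AGHMT, a name that follows the label, which the Akt1 counts go against), and isolated adult ventricular cardiomyocytes (CM). The treatment note of the labels names Akt, and the title of the series names Akt1. GHMT and AGHMT cells were sorted on the Myh6 promoter reporter. Per the labels, RNA was extracted with TRIzol and libraries were made with a stranded TruSeq kit, and per the submitters' processing notes reads were aligned to mm10 with Bowtie2 2.0.6, counted with HTSeq and normalised with DESeq. The strand setting of the counting and the annotation version are not given in the sources used here. The deposited files of each library hold counts of reads per Ensembl gene, with reads that matched several places not counted. A further deposited table holds the normalized signal of all libraries, which the authors made by dividing the counts by 1 size factor per library. Division of each column by its smallest value gave whole numbers (tolerance 0.001) whose totals equalled those of the count files. The counts were tested, and the normalized values served as an alternative.

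Of 43629 gene identifiers in the count files, 42462 were matched to a symbol and position in GENCODE M21 (GRCm38, the same build as mm10). Gene reads per library numbered 1872558 to 2200815 in GHMT, 14386407 to 18493989 in AGHMT, 5120230 to 15952646 in CM and 15971154 to 33552138 in E. Reads in no annotated gene were 8.45% to 20.2% of uniquely aligned reads. Shares of a single library carry a Wilson 95% interval, and the floor of a gene without reads is 3 counts pooled over the 3 libraries of a group. Pairs of replicates differed beyond counting error, with a chi-square per degree of freedom of at least 15.0.

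Genes were kept with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which left 15059. Libraries were scaled by the trimmed mean of M values (TMM), and the factor of GHMT 1 was 0.347. All 12 libraries entered 1 robust quasi-likelihood fit, and 6 pairs of groups were compared with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over all genes, with a threshold of 0.05. CPM values are on the TMM scale, and log2 values use a prior count of 2. Lists of genes were fixed before the data were examined, as were the groups, the tests, the rule for naming genes and the alternatives listed first below. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the lists of a comparison), beside camera with an estimated correlation and fry. Fry asks whether the members of a list move one way on balance and does not compare them with other genes. A library's position between E and CM is the least-squares coefficient of its log2 CPM minus the E mean on the CM mean minus the E mean. It uses genes that pass in CM against E with at least 2-fold change, without the forced genes, and groups were compared by an exact two-sided permutation test, whose smallest p is 0.1. Genes that pass in CM against E with at least 2-fold change were also counted in the other comparisons, and groups simulated without change were counted in the same way. The first 2 principal components of the 500 most variable genes held 62.5% and 24.7% of the variance.

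Genes named in the text follow a rule. It takes the 5 forced genes, genes of the Akt pathway, among them Akt2, Foxo1, Foxo3, Mtor and Igf1r, and Myh6 with a statement of the sort. From each list it takes the member with the highest mean log2 CPM and up to 3 passing members with the largest absolute log2 fold change, 4 in all, in AGHMT against GHMT, GHMT against E and CM against E. In the other comparisons it does so only from sarcomere, calcium, fibroblast, mitosis and fatty acid genes. It adds the 8 largest changes per direction in AGHMT against GHMT, and 5 in the others, that pass with a mean of at least 10 CPM and groups that do not overlap, predicted genes and pseudogenes left out. Of the genes so named, the text gives those of most interest, and some are not reported here. Genes with 1 to 3 reads in the lower group are not given with values. Where 5 or fewer members of a list passed in 1 direction, those named in addition were chosen after their values were seen, as were Hcn4 in AGHMT against GHMT and Lum and Dcn against E.

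Alternatives chosen before the counts were read were DESeq2's size factors in edgeR, total counts, normalisation without mitochondrially encoded genes, no filter, a stricter filter (above 1 CPM in 3 libraries), DESeq2 1.42.0, limma on the log2 of the deposited normalized values plus 1, only the 2 groups compared, the replicate number as a block, glmTreat at 1.5-fold, a 4-fold axis, an axis without mitochondrial and oxidative phosphorylation genes, a prior count of 0.5, and each library left out. No label says that the replicate numbers pair libraries, so the block is given only as an alternative. Added after the data were seen were a correction of each library for GC content (smooth with span 0.4 over genes with a mean log2 CPM over 2), thinning to 612458 non-mitochondrial reads, leaving out GHMT 1, E 1 and CM 3 together, and counts recovered from the normalized values. In a test on simulated data shaped like AGHMT and GHMT, the quasi-likelihood test recovered 6% of genes changed 2-fold, 55.2% of genes changed 4-fold and 95.5% of genes changed 8-fold. The changed genes were drawn only from those abundant enough to be read in the shallowest library. Recovery of low genes was not simulated. Simulated axis positions of 0.3 and 0.6 came back as 0.27 and 0.58. Computations ran in R 4.3.3 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9).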

Results

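The series asks whether adding the kinase gene Akt1 to a set of heart transcription factors improves the conversion of fibroblasts to heart muscle cells. Mouse embryonic fibroblasts had carried an empty vector (E), the factors Gata4, Hand2, Mef2c and Tbx5 (GHMT), or the same factors with Akt1 (AGHMT) for 3 weeks. Isolated adult ventricular cardiomyocytes (CM) were the reference. Each group had 3 libraries. By their labels, the GHMT and AGHMT cells were sorted on a fluorescent reporter driven by the promoter of Myh6, the main myosin heavy chain of the adult mouse heart, and the labels of E and CM name no sort. In every comparison of GHMT or AGHMT with E, the effect of the sort and that of the factors therefore cannot be told apart. No label says whether the replicates were separate cultures or animals. Each p-value therefore sets a difference against the spread among these libraries, which may not cover that among cultures or animals. In the main fit that spread was estimated over all 12 libraries together, not only those of the 2 groups compared. Expression is given as normalised counts on edgeR's CPM scale (CPM), mean ± SD with n = 3 per group, and the difference between 2 groups as a log2 fold change with its standard error (SE).

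Mitochondrially encoded transcripts, which code for core parts of the respiratory chain, made up very different shares of the libraries. They were 3.65% to 7.36% of gene reads in E, 36.6% to 42.7% in AGHMT, 40.0% to 59.9% in CM and 27.8% to 72.2% in GHMT. A single gene, mt-Nd6, took 43.1% of the reads of GHMT 1 (Wilson 95% interval 43.03 to 43.16%), 14% of GHMT 3 (13.95 to 14.05%) and 3.34% of GHMT 2 (3.32 to 3.37%). The strand setting of the counting is not given, so reads of mt-Nd6 cannot be told from reads of the opposite strand. The GHMT libraries were shallow, with 612458, 1534409 and 991665 reads in all other genes, against 8238918 to 11026245 in AGHMT, 3074424 to 7174467 in CM and 14956733 to 32328579 in E. A gene with 3 reads stood at 3.93, 1.56 and 2.06 CPM in GHMT 1 to 3, but at 0.16 to 0.23 CPM in the AGHMT libraries. Low expression could therefore be measured in AGHMT where it could not be detected in GHMT. Such intervals and floors cover counting error only.

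**Figure D1:**
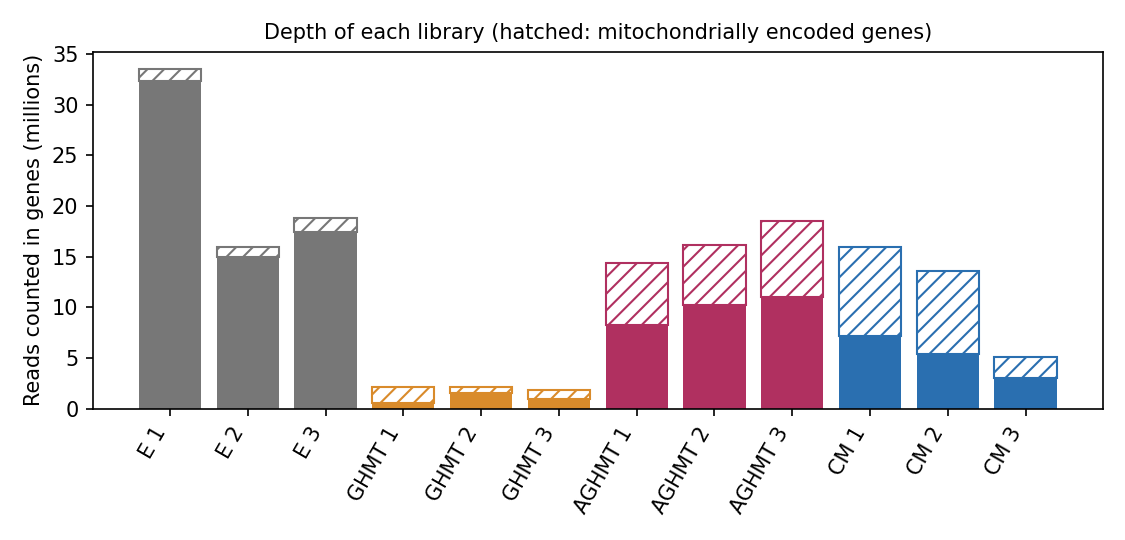
Reads counted in genes for each of the 12 libraries, with the hatched part of each bar showing reads of mitochondrially encoded genes. The 3 GHMT libraries hold 1872558 to 2200815 gene reads, and the others 5120230 to 33552138.

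Tbx5 and Mef2c, which encode transcription factors of the developing heart, stood above E in both sorted groups. Tbx5 stood at 154 ± 22.4 CPM in GHMT, 92.6 ± 25 in AGHMT, 19.1 ± 2.0 in CM and 4.07 ± 0.882 in E. Mef2c stood at 218 ± 27.9 CPM in GHMT, 165 ± 9.81 in AGHMT, 106 ± 43.7 in CM and 15 ± 2.12 in E. Gata4 was low but above E, with 7.92 ± 6.83 CPM in GHMT and 9.70 ± 1.95 in AGHMT against 0.174 ± 0.152. Against E these 3 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment in both groups, with every sorted library above every E library. Gata4 lost its call in AGHMT after thinning (adjusted p = 0.157). Tbx5 rose by 5.23 (adjusted p = 1.09e-07) in GHMT and 4.50 (2.89e-07) in AGHMT, Mef2c by 3.86 (1.5e-06) and 3.46 (3.39e-06), and Gata4 by 5.49 (2.43e-04) and 5.69 (1.85e-04) on the log2 scale. Hand2 did not pass in either group. Its log2 fold change was 1.29 (adjusted p = 0.166) in GHMT, where the groups overlapped, and 1.40 (adjusted p = 0.115) in AGHMT. It passed in both after a correction for GC content, at adjusted p = 4.52e-05 and 5.91e-05, and without the 3 libraries that stood apart (0.00737 and 0.00555), and in AGHMT with only the 2 groups compared (0.0304), within ranges over all alternatives of 4.52e-05 to 0.976 and 5.91e-05 to 0.918.

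Akt1 encodes a kinase that passes on growth factor signals, and its counts went against the AGHMT label. Akt1 (ENSMUSG00000001729, mm10 chromosome 12, 112653821 to 112674884) had 7.30, 12 and 19.6 CPM in AGHMT 1 to 3, from 95, 218 and 360 reads. In GHMT 1 to 3 it had 1.31, 13.6 and 13.8 CPM, from 1, 26 and 20 reads. The E libraries held 104, 64.1 and 21.0 CPM and the CM libraries 23.8, 18.1 and 104. By the quasi-likelihood test Akt1 did not differ between AGHMT and GHMT, at 13.0 ± 6.22 against 9.54 ± 7.12 CPM (log2 fold change 0.34, SE 0.79, adjusted p = 0.786, groups overlapping), and the upper 95% bound of that log2 fold change was 1.92. Against E, Akt1 was lower in AGHMT (-2.27, adjusted p = 0.0227) and in GHMT (-2.62, adjusted p = 0.0146), with 3 of 3 libraries below every E library in each. The AGHMT call ended with a fold of similar size without AGHMT 1 (-1.98, adjusted p = 0.0977), AGHMT 2 (-2.21, 0.0706), AGHMT 3 (-2.52, 0.0583) or E 1 (-1.65, 0.147) and with limma on the deposited values (-2.44, 0.0791). It ended with a smaller fold after the GC correction (-0.43, adjusted p = 0.389) and thinning (-0.83, 0.806), within a range over all alternatives of 3.4e-05 to 0.806. The GHMT call ended after the GC correction (-0.06, adjusted p = 0.921) and thinning (-1.46, 0.496), within a range of 6.9e-06 to 0.921. No library of the group exceeded any E library in Akt1, so its members are called AGHMT-labelled below, and every direction drawn from that group rests on the label. None of the 5 forced genes differed between AGHMT-labelled and GHMT libraries in the quasi-likelihood test. Log2 fold changes were -0.73 for Tbx5 (adjusted p = 0.111), -0.40 for Mef2c (0.388), 0.20 for Gata4 (0.871) and 0.12 for Hand2 (0.927). Tbx5 passed as lower with DESeq2 (-0.88, adjusted p = 0.0371) and after the GC correction (-1.71, adjusted p = 0.00191), and over the alternatives its adjusted p ranged from 0.00191 to 0.864.

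**Figure D2:**
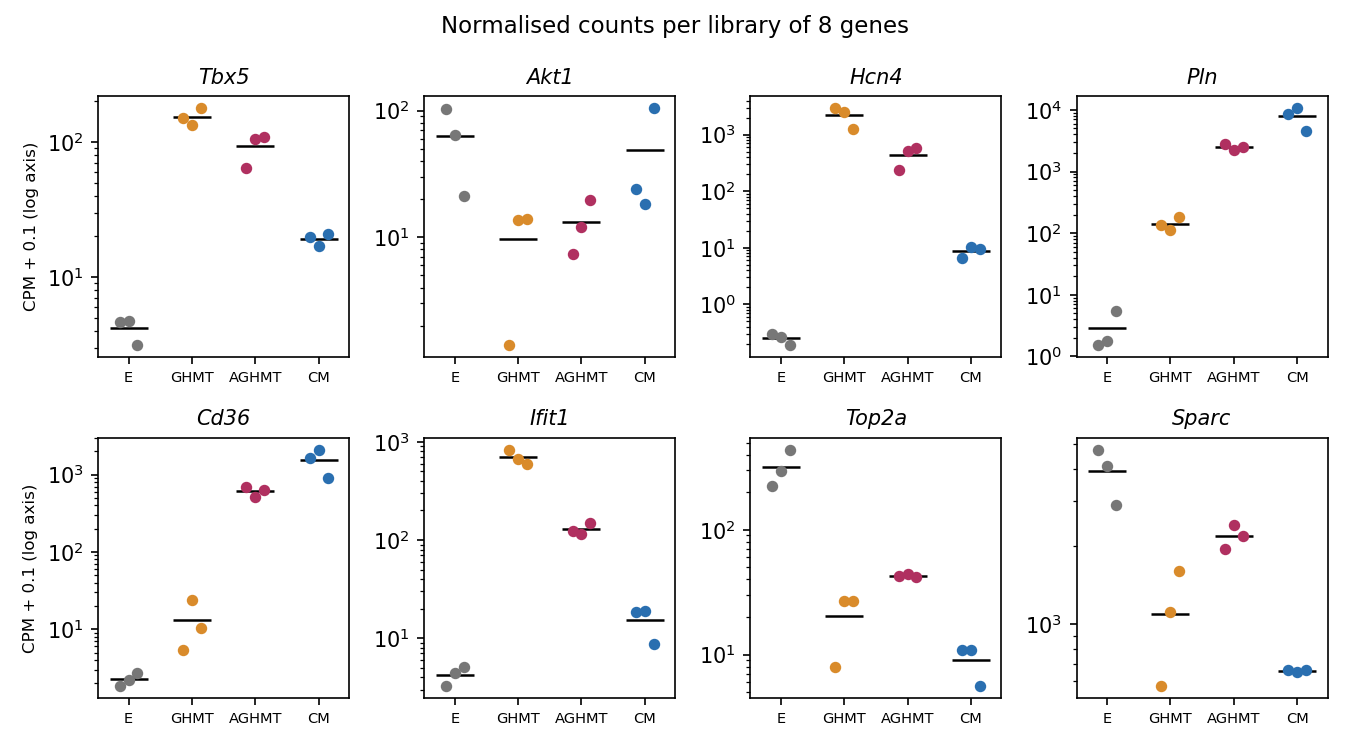
Normalised CPM plus 0.1, on a log axis, of 8 genes in each of the 12 libraries (points) with the mean of each group (bar). Tbx5 stood at 154 CPM in GHMT and 92.6 in AGHMT against 4.07 in E, while Akt1 had 9.54 CPM in GHMT, 13.0 in AGHMT and 62.9 in E.

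Adult cardiomyocytes and empty-vector fibroblasts differed in contraction, energy and matrix genes, which sets the scale for the reprogrammed groups. Myh6 (ENSMUSG00000040752, mm10 chromosome 14, 54941921 to 54966927) stood at 7423 ± 8650 CPM in CM and 0.986 ± 0.529 in E, a log2 fold change of 12.89 (SE 1.06, adjusted p = 2.8e-07). Myl2, the regulatory light chain of ventricular myosin, rose by 12.33 on the log2 scale to 9435 ± 4108 CPM, and Mybpc3 by 12.58 to 1185 ± 993 CPM. The phospholamban gene Pln, which restrains the calcium pump, stood at 7954 ± 3059 CPM against 2.80 ± 2.14. The pump itself, Atp2a2, rose from 256 ± 41.0 to 10520 ± 2960 CPM (log2 fold change 5.36, SE 0.33, adjusted p = 1.23e-08). The fatty acid transporter gene Cd36 rose from 2.16 ± 0.430 to 1546 ± 604 CPM and the ATP synthase gene Atp5a1 from 270 ± 59.0 to 3368 ± 145 CPM. In the other direction, the collagen gene Col12a1 stood at 4.90 ± 0.135 CPM against 3454 ± 272 (-9.46, SE 0.33, adjusted p = 2.72e-10), the collagen cross-linking gene Lox at 7.97 ± 3.13 against 2962 ± 622, and the topoisomerase gene Top2a of dividing cells at 9.02 ± 3.05 against 320 ± 109. Irx4, a ventricular transcription factor, had 15.7 ± 10.1 CPM in CM and no read in E, at least 540-fold higher over a floor of 3 reads pooled over the 3 E libraries. For each gene named here the 3 CM libraries lay apart from the 3 E libraries, and the largest adjusted p was 2.47e-05. Of the forced genes, Gata4 (7.83), Mef2c (2.82), Tbx5 (2.23) and Hand2 (2.95) were higher in CM, Hand2 at adjusted p = 0.00486, while Akt1 did not differ (-0.38, adjusted p = 0.703, groups overlapping). In the quasi-likelihood test Hand2 lost its call with total counts (2.15, adjusted p = 0.0629) and after thinning (0.673), and Tbx5 after thinning (0.058).

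Of 15059 genes tested, 2933 were higher and 3386 lower in CM than in E, so 46.4% of the calls were higher. That share was 58.3% with DESeq2's size factors in edgeR, 60.9% with DESeq2, 56.8% with limma on the deposited normalized values, 22.7% with total counts, 59.6% after the GC correction and 65.2% after thinning all libraries to 1 depth. By abundance, 54.4% of the calls were higher at a mean log2 CPM up to 2 and 32.3% above 5. The groups did not overlap for 57.2% of genes, where chance gives 10%. Here and below, that 10% holds only for libraries that could be exchanged between the groups, while depth also differed between groups. All 28 sarcomere genes tested were higher (28 adjusted over the list alone, camera adjusted p = 3.13e-25), as were 35 of 36 calcium handling and ion channel genes (3.91e-24), 72 of 78 nuclear-encoded oxidative phosphorylation genes (73 adjusted over the list alone, 1.56e-20), 29 of 31 fatty acid oxidation genes (6.67e-15) and 20 of 20 genes of the tricarboxylic acid cycle (2.08e-11). Of 37 fibroblast and matrix genes 33 were lower (8.37e-15), and so were 29 of 30 mitosis genes (1.6e-13). Of 31 lists, 26 passed camera and 20 of these held with an estimated correlation, those named here among them. Marker genes of other heart cells stood out as well, since 14 of 14 endothelial genes (1.34e-09) and 14 of 17 macrophage genes (5.03e-07) were higher than in E, with Pecam1 of endothelium at 107 ± 42.1 against 0.132 ± 0.098 CPM.

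In the sorted GHMT cells, several ion channel and transcription factor genes of the heart stood far above E, whose labels name no sort. The pacemaker channel gene Hcn4 stood at 2239 ± 861 CPM in GHMT and 0.154 ± 0.056 in E, a log2 fold change of 13.71 (SE 0.63, adjusted p = 3.13e-09). Kcnj5 and Kcnj3, potassium channel genes of the atrium and sinus node, rose by 10.58 and 10.35 on the log2 scale. The transcription factor gene Tbx20 rose from 0.861 ± 0.182 to 1302 ± 280 CPM, the coactivator gene Myocd from 1.19 ± 0.342 to 296 ± 174, and Tbx18, of sinus node and epicardium, from 22.3 ± 4.90 to 350 ± 26.6. Among sarcomere genes, Ldb3 of the Z-disc reached 1018 ± 243 CPM against 4.59 ± 0.444, but Myl2 only 41.2 ± 35.4 and Myh6, on whose reporter the cells were sorted, 47.7 ± 21.8 against 0.986 (log2 fold change 5.63, SE 0.82, adjusted p = 9.65e-05). Atp2a2 rose by 3.31 on the log2 scale to 2550 ± 443 CPM. The fibroblast genes S100a4 (16.4 ± 2.86 against 808 ± 461 CPM) and Pdgfrb (2.66 ± 0.0788 against 118 ± 82.1) fell, and so did Top2a (20.4 ± 10.9 against 320 ± 109). The mitotic kinase gene Plk1 had no read in GHMT and was at least 19.0-fold lower. The interferon response gene Ifit1 rose from 4.18 ± 0.951 to 696 ± 124 CPM (log2 fold change 7.38, SE 0.42, adjusted p = 1.49e-08), although Ifit genes share sequence and reads that match several places were not counted. The 3 GHMT and 3 E libraries did not overlap for any gene named here, and the largest adjusted p was 7.43e-04. After thinning Pdgfrb lost its call in the quasi-likelihood test (adjusted p = 0.0545).

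In all, 2979 genes were higher and 4948 lower in GHMT than in E by the quasi-likelihood test, so 37.6% of the calls were higher. That share was 12% with total counts, 23.6% with limma on the deposited values, 52.3% after the GC correction and 68.2% after thinning. It depended on abundance, with 619 higher and 2864 lower genes (17.8% higher) at a mean log2 CPM up to 2, but 1420 and 455 (75.7%) above 5. For 1354 called genes the lower group had no read. The excess of lower calls therefore cannot be told apart from the shallow GHMT libraries. Higher calls fell to 1658 without E 1 and to 1951 without AGHMT 3, which enters the shared filter and normalisation. Groups did not overlap for 59.5% of genes (chance 10%). Of 28 sarcomere genes 20 were higher (21 adjusted over the list alone, camera adjusted p = 7.91e-12, 0.0452 with an estimated correlation) and 1 was lower, the skeletal actin gene Acta1, with no read in GHMT. In the quasi-likelihood test Acta1 lost its call without GHMT 2 (adjusted p = 0.0507), after the GC correction (0.0716) and after thinning (0.189). Of 36 calcium handling and channel genes 22 were higher (23 adjusted over the list alone, 3.04e-11). All 28 mitosis genes that passed, of 30, were lower (4.89e-06), as were the 26 of 30 DNA replication genes that passed (2.77e-05), and 11 of 22 interferon response genes were higher (6.95e-06). These lists held with an estimated correlation. Of 37 fibroblast and matrix genes 25 were lower (26 adjusted over the list alone) and 2 were higher, Lum (log2 fold change 3.58, adjusted p = 5.43e-06) and Dcn (2.71, 1.23e-05), small leucine-rich proteoglycans named after their values were seen, both in 3 of 3 libraries. That list had a camera adjusted p of 0.0227 but 0.449 with an estimated correlation, and lost its call without GHMT 2 (0.0584), without GHMT 3 (0.0941) and after the GC correction (0.185), within a range over camera's alternatives of 2.19e-04 to 0.449. Of 10 mitochondrially encoded mRNAs 9 were higher (4.25e-06, adjusted p = 0.109 with an estimated correlation), while nuclear-encoded oxidative phosphorylation genes split into 6 higher and 35 lower of 78 and did not pass as a list (0.262).

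The libraries labelled AGHMT also rose above E in heart genes, among them genes of working heart muscle. The actin filament gene Lmod2 stood at 89.5 ± 2.71 CPM against 0.217 ± 0.162 in E (log2 fold change 8.73, SE 0.52, adjusted p = 2.14e-08), the slow myosin gene Myh7 at 27.7 ± 3.64 against 0.0632 ± 0.0512, and Xirp2 at 107 ± 8.04 against 0.299 ± 0.163. Myh6, the gene of the sort reporter, stood at 145 ± 67.8 CPM (log2 fold change 7.21, SE 0.86, adjusted p = 2.09e-05). Trdn, which anchors calcium release channels, reached 360 ± 60 CPM against 0.195 ± 0.151, Hcn4 reached 439 ± 175 and Kcnj5 376 ± 57.6. Atp2a2 rose by 3.65 (SE 0.30) to 3223 ± 216 CPM, the lipase gene Lpl from 74.1 ± 2.45 to 2857 ± 583, and Cd36 from 2.16 to 612 ± 94.3. Tecrl, a reductase gene of heart muscle, had 36.8 ± 7.52 CPM and no read in E, at least 1490-fold higher. S100a4 fell from 808 to 22.4 ± 13.0 CPM and Top2a from 320 to 42.9 ± 1.58. The mast cell protease gene Mcpt4 had 322 ± 15.5 CPM against 0.0958 ± 0.0494. No AGHMT-labelled library overlapped an E library for these genes, whose largest adjusted p was 9.5e-05. After thinning Tecrl (adjusted p = 0.0606) and Top2a (0.0701) lost their calls in the quasi-likelihood test. The abundant tropomyosin gene Tpm1 did not differ (0.26, adjusted p = 0.482, groups overlapping; GC correction 0.62, 0.0324, range over alternatives 0.0324 to 0.861).

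The quasi-likelihood test called 3292 genes higher and 3706 lower against E, 47% of them higher, against 23.3% with total counts and 75.5% after thinning. By abundance, 35.6% of the calls were higher at a mean log2 CPM up to 2 and 78.9% above 5. Lower calls were 2009 without AGHMT 1, 1670 without AGHMT 3 and 1915 without E 1. The groups did not overlap for 71.6% of genes, against 10% by chance. Of 28 sarcomere genes 25 were higher (25 adjusted over the list alone, camera adjusted p = 4.93e-16) and Acta1 alone was lower. Of 36 calcium handling and channel genes 29 were higher (4.93e-16) and 8 of 8 ventricular genes were too (3.97e-06). Of 30 mitosis genes 28 were lower (2.11e-11), and these 4 lists held with an estimated correlation. Lists that passed only with the preset correlation included fibroblast and matrix genes, with 25 of 37 lower (27 adjusted over the list alone, 4.31e-07, adjusted p = 0.0614 with an estimated correlation) and Lum (3.94, 2.51e-06) and Dcn (2.36, 4.17e-05) again higher. Fatty acid oxidation had 15 genes higher and Etfb lower of 31 (4.71e-04, adjusted p = 0.0614 with an estimated correlation), and the endothelial list had 11 higher and Eng lower of 14 (0.00172, adjusted p = 0.108 with an estimated correlation).

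**Figure D3:**
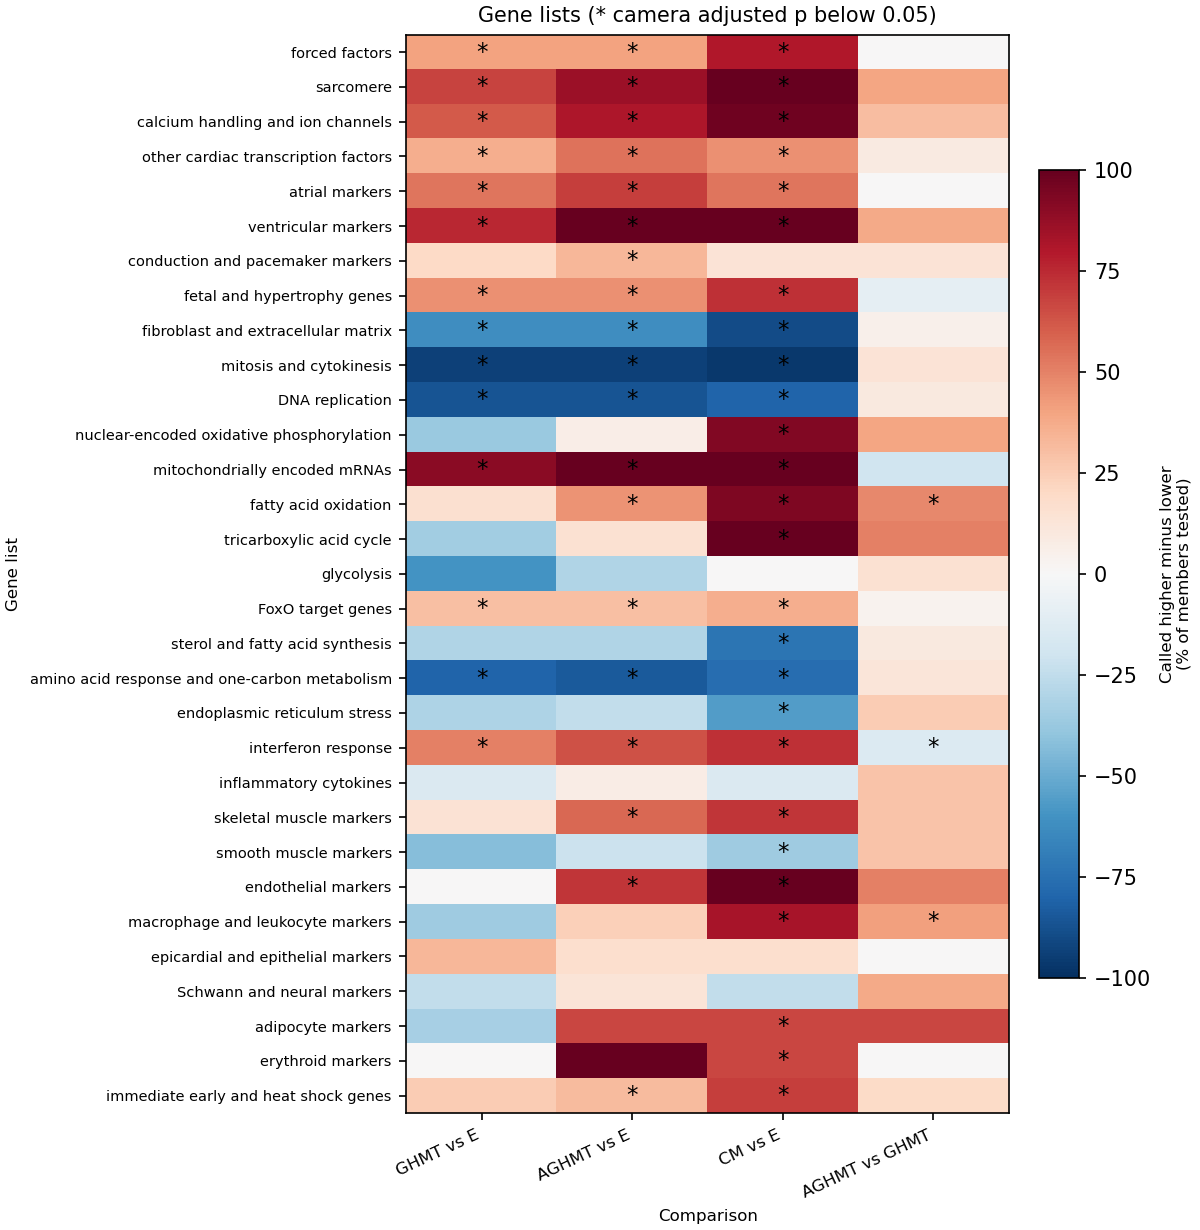
Gene lists against 4 comparisons, coloured by the number of members higher minus the number lower as a percentage of members tested, with an asterisk where camera passed at an adjusted p below 0.05. Sarcomere genes were 20 higher and 1 lower of 28 in GHMT against E, 25 and 1 in AGHMT against E, and 28 and 0 in CM against E, while only 3 lists passed in AGHMT against GHMT.

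Between the sorted groups, AGHMT-labelled libraries had more of several contraction and fat-burning transcripts and less of a few interferon response transcripts than GHMT libraries. Cd36 stood at 612 ± 94.3 against 13.2 ± 9.69 CPM, 43.3-fold higher (log2 fold change 5.44, SE 0.49, adjusted p = 4.98e-05). Pln stood at 2483 ± 274 against 143 ± 34.0 CPM (4.12, SE 0.49, adjusted p = 2.91e-04). Myh7 (4.87, adjusted p = 1.97e-04), Xirp2 (4.53, 1.98e-04), Lmod2 (3.99, 1.98e-04) and the muscle methyltransferase gene Smyd1 (3.87, 1.30e-04) rose too. Ppara, the nuclear receptor that controls fatty acid oxidation, had 3.21 ± 0.322 CPM and no read in GHMT, at least 4.48-fold higher (adjusted p = 0.00845). Atp5a1 rose from 104 ± 88.3 to 489 ± 55.7 CPM (2.21, SE 0.46, adjusted p = 0.00602) and the malate dehydrogenase gene Mdh1 from 29.6 ± 17.0 to 158 ± 41.1. Lower in AGHMT-labelled libraries were Ifit1, at 129 ± 17.2 against 696 ± 124 CPM (-2.43, SE 0.33, adjusted p = 5.81e-04), Ifi44, at 16.8 ± 0.302 against 118 ± 24.4 (-2.81, 5.7e-04), and the matrix protein gene Thbs1, at 1426 ± 95.5 against 5185 ± 478 (-1.86, 0.0019). The histone demethylase gene Kdm6b stood at 18.0 ± 6.35 against 288 ± 125 CPM. Hcn4, named after its value was seen, fell from 2239 ± 861 to 439 ± 175 CPM (-2.35, adjusted p = 0.00188). These directions were shown by 3 of 3 libraries of each group. After thinning Mdh1 (2.39, adjusted p = 0.324, range over alternatives 4.24e-08 to 0.324), Ifi44 (-3.74, 0.407, range 1.89e-23 to 0.407) and Hcn4 (-2.17, 0.239, range 2.46e-08 to 0.239) lost their calls.

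Further genes, of these and other programmes, did not pass, or lost the call without 1 library. Myh6 stood at 145 ± 67.8 against 47.7 ± 21.8 CPM in cells sorted on its reporter and did not pass (1.58, SE 0.68, adjusted p = 0.117). It passed without the filter (5.07e-05), with only these 2 groups (0.0461) and without the 3 libraries that stood apart (0.0374), within a range of 5.07e-05 to 0.728. Atp2a2 stood at 3223 ± 216 against 2550 ± 443 CPM (0.34, adjusted p = 0.405) and passed only without mitochondrially encoded genes (0.047, range 0.047 to 0.934). Myl2, 228 ± 107 against 41.2 ± 35.4 CPM (2.43, adjusted p = 0.0127), lost its call without GHMT 2 (2.26, adjusted p = 0.0507) or AGHMT 2 (2.02, adjusted p = 0.06), within a range of 2.12e-11 to 0.149. The chaperone gene Canx (-1.86, adjusted p = 0.00399) and the secreted factor gene Fstl1 (-1.89, 0.00188) lost theirs without AGHMT 3 (-1.11, adjusted p = 0.0931, range 1.78e-07 to 0.0931, and -1.16, adjusted p = 0.0535, range 8.34e-08 to 0.0535), where the median of all genes moved by 0.625. Ifit2 (-1.70, adjusted p = 0.00591) did so without AGHMT 3 (-1.04, adjusted p = 0.126) and with total counts (0.0733), within a range of 1.89e-10 to 0.454. Ankrd1, Nppa, Actn1, Lpl, Sparc, Klf6 and Foxo3 passed at adjusted p between 0.0156 and 0.0481, but each missed the threshold without AGHMT 2, at adjusted p between 0.0555 and 0.145. Their log2 fold changes there were -0.80, -1.37, -1.48, 1.18, 0.93, -1.12 and 1.11, against -0.85, -1.47, -1.62, 1.02, 1, -1.18 and 1.01 with all libraries, but Foxo3 was 0.07 and Sparc 0.15 after the GC correction, and Ankrd1 was -0.24 and Klf6 -0.46 without AGHMT 3. Over all alternatives their adjusted p ran from 5.28e-10 for Ankrd1 to 0.881 for Foxo3.

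By the quasi-likelihood test, 1993 genes were higher and 689 lower in AGHMT-labelled than in GHMT libraries, 74.3% of them higher. That share was 49.1% after the GC correction, 53.4% in the reported draw of the thinning (the lowest of 5 draws, with a median of 63.2%), 56.7% with DESeq2, 63.7% with DESeq2's size factors in edgeR, 90.4% without mitochondrially encoded genes and 95.4% with total counts. It also depended on abundance, with 90.6% higher among calls at a mean log2 CPM up to 2, 77.8% between 2 and 5, and 38.6% above 5. Thinned to the 612458 non-mitochondrial reads of GHMT 1, the comparison gave 39 higher and 34 lower genes, and 13 of 46 named genes kept their call. The counts were 1127 higher and 250 lower without AGHMT 1, 865 and 172 without AGHMT 2, 2903 and 91 without AGHMT 3, and 3851 and 222 without E 1, and without GHMT 3 the lower count was 1060. Groups did not overlap for 45.9% of genes against 10% for exchangeable libraries, and for 658 genes the lower group had no read. The shallow GHMT libraries can raise the 45.9% without a change in expression, so the 10% is no measure of chance here.

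As a list, fatty acid oxidation was higher in AGHMT-labelled than in GHMT libraries, with 15 higher and 0 lower of 31 genes (18 adjusted over the list alone, camera adjusted p = 0.0358), but not with an estimated correlation (0.5). It lost its call also without GHMT 2 (0.237), AGHMT 1 (0.0578) or AGHMT 2 (0.0718), within a range over camera's alternatives of 0.00206 to 0.5. The interferon response was lower by camera (0.00529) but not with an estimated correlation (0.385, range over camera's alternatives 0.0015 to 0.385) or by fry, which tests against no change (0.277), with 4 genes of 22 lower, Ifit1, Ifit2, Ifi44 and Ifih1, and Mx1 higher, the same numbers adjusted over the list alone. Macrophage markers were higher, with 7 of 17 (7 adjusted over the list alone, 0.00529), but not without GHMT 2 (0.0804) or with an estimated correlation (0.5, range over camera's alternatives 0.0012 to 0.5). Sarcomere genes had 12 higher and Ldb3 lower of 28 (14 and 1 adjusted over the list alone) and did not pass (0.0749), nor did calcium handling and channel genes with 12 higher and Hcn4 lower of 36 (14 and 2 adjusted over the list alone, 0.223). Oxidative phosphorylation, with 31 higher of 78 (33 adjusted over the list alone, 0.0749), the tricarboxylic acid cycle, with 10 of 20 (13 adjusted over the list alone, 0.0749), and mitosis, with Cdk1, Racgap1, Tpx2 and Hmmr higher of 30 (3 adjusted over the list alone, 0.55), did not pass either. After thinning Cdk1 turned lower without passing the quasi-likelihood test (adjusted p = 0.925), and Tpx2 lost its call (0.176). FoxO target genes, which Akt signalling is known to silence, were 4 higher (Erbb3, Fbxo32, Trim63 and Sesn1) and 3 lower (Cdkn1b, Cat and Klf6) of 30, with 6 and 4 adjusted over the list alone (0.0749). The median or mean of this list differed in sign from the camera test, as they did for other cardiac transcription factors, atrial, fetal, fibroblast, sterol, amino acid, endoplasmic reticulum and immediate early genes and the forced factors.

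Placed on a line from the E mean (0) to the CM mean (1) by 6193 genes at least 2-fold apart between them, GHMT libraries lay at 0.32 ± 0.012 and AGHMT-labelled libraries at 0.496 ± 0.005. The difference of 0.176 had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 can give. On the 2895 genes higher in CM, such as sarcomere genes, GHMT lay at 0.073 ± 0.083 and AGHMT-labelled at 0.556 ± 0.022. On the 3298 genes lower in CM, such as matrix and mitosis genes, the order was the other way, with 0.69 ± 0.114 for GHMT and 0.406 ± 0.021 for AGHMT-labelled libraries. Both differences moved with the setting. That for genes higher in CM, 0.484, was 0.189 after thinning and 0.345 after the GC correction, and that for genes lower in CM, -0.284, was 0.044 and -0.158. Both settings chose the genes again from their own CM against E calls. After thinning these were 693 higher and 370 lower before the 2-fold cut. A change of genes therefore cannot be told apart from depth or GC content in these values. With the genes kept, the values also depended on abundance. Among abundant genes, with a mean log2 CPM over 5, the values for genes higher in CM were 0.612 ± 0.033 in GHMT and 0.791 ± 0.002 in AGHMT-labelled libraries. For genes lower in CM they were 0.104 ± 0.038 and 0.147 ± 0.01 (exact permutation p = 0.2), so the order turned there. At a mean log2 CPM up to 2 they were -0.126 ± 0.076 and 0.466 ± 0.03 for genes higher in CM, and 1.027 ± 0.123 and 0.553 ± 0.034 for genes lower in CM. The higher GHMT position on genes lower in CM was thus not seen in abundant genes, and the shallow GHMT libraries limit what low genes show. Of the genes higher in CM, 861 (29.7%) were also called higher in GHMT than in E and 432 (14.9%) lower, and in AGHMT-labelled libraries 1682 (58.1%) were higher and 76 (2.6%) lower. Of the genes lower in CM, 1589 (48.2%) were lower and 455 (13.8%) higher in GHMT, and 1398 (42.4%) lower and 248 (7.5%) higher in AGHMT-labelled libraries. These shares of lower genes were 23.5% and 16.8% after thinning, and the latter was 27.1% without AGHMT 3, with genes chosen again in each setting. In groups simulated without change against the same E libraries, the quasi-likelihood test called 0 of the genes higher or lower in CM, with means of 0.21% to 1.85% at an unadjusted p under 0.05, and no other tool was run on them. That 0 stands for groups without any change. Calls spread evenly over all genes tested would have shared 573 genes higher and 1084 lower in CM for GHMT. For AGHMT-labelled libraries these numbers were 633 and 812. Between the sorted groups, 775 (26.8%) of the genes higher in CM were higher in AGHMT-labelled libraries and 89 lower. Without AGHMT 2 the share was 14.5%, without AGHMT 1 16.9%, without E 1 40.5% and after thinning 5.4%, each with genes chosen again. Of the genes lower in CM, 216 (6.5%) were lower and 334 (10.1%) higher. Over all 15059 genes tested, 1993 were higher and 689 lower in this comparison. The share of 6.5% was 0.8% without AGHMT 3, 3% after thinning, 10.6% with DESeq2's size factors in edgeR, 14.4% with DESeq2 and 14% after the GC correction, with genes chosen again except with DESeq2. As sets, the genes higher in CM rose (camera adjusted p = 1.25e-07, 0.0207 with an estimated correlation), and the genes lower in CM passed as lower (0.0127, 0.279 with an estimated correlation). Camera compares a set with other genes, and the median log2 fold change of the latter set, 0.33, was below the 0.634 of all genes tested.

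**Figure D4:**
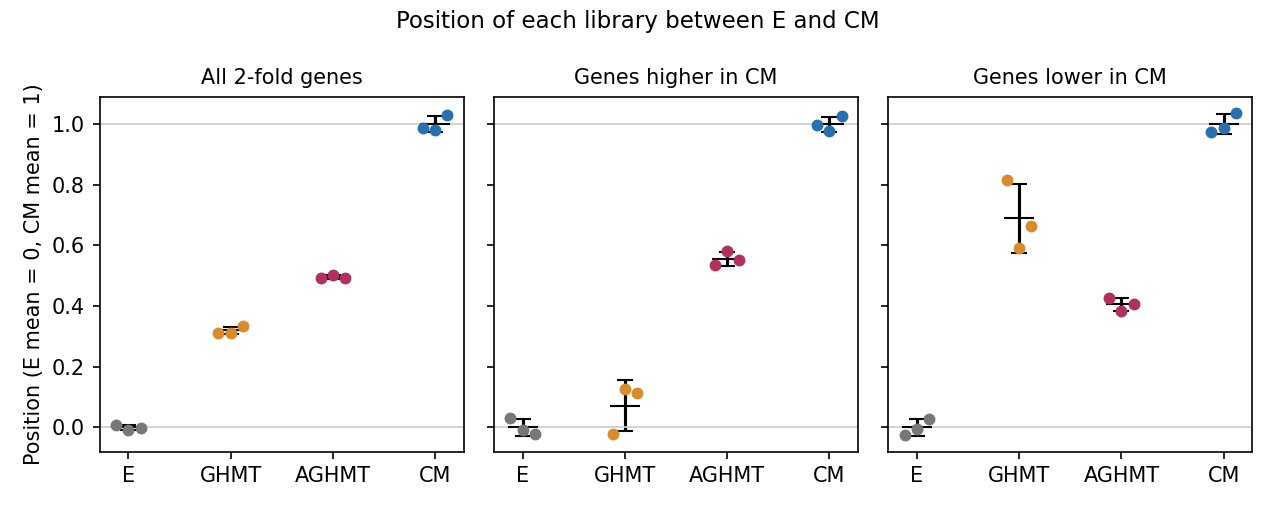
Position of each library (points) between the E mean (0) and the CM mean (1), without unit, with the group mean ± SD (bar), for all 2-fold genes, genes higher in CM and genes lower in CM. AGHMT-labelled libraries lie at 0.493 to 0.502 and GHMT libraries at 0.313 to 0.334 for all genes. For genes lower in CM the order is the other way, and there it turned after thinning, with genes chosen again from the thinned calls. It also turned among genes lower in CM with a mean log2 CPM over 5, at 0.104 for GHMT and 0.147 for AGHMT-labelled libraries.

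Against adult cardiomyocytes, both sorted groups were far lower in contraction and energy genes and higher in fibroblast genes. Myh6 had a log2 fold change of -7.26 in GHMT (SE 0.86, adjusted p = 9.29e-06) and of -5.68 in AGHMT-labelled libraries (SE 0.79, adjusted p = 8.24e-05), both sorted on its reporter. Tpm1 had log2 fold changes of -2.95 and -2.22 and Atp2a2 of -2.04 and -1.71. In AGHMT-labelled libraries the troponin gene Tnni3 stood at 17.0 against 1661 CPM (-6.60), Tcap of the Z-disc at 1.15 against 354 (-8.25) and the respiratory chain gene Cox6a2 at 0.918 against 582 (-9.30, adjusted p = 6.71e-05). Lox was higher than in CM, with 996 against 7.97 CPM in GHMT (6.95) and a log2 fold change of 6.55 in AGHMT-labelled libraries, as did Thbs1 (7.44 and 5.58). Hcn4 was at 439 CPM in AGHMT-labelled libraries and 8.78 in CM (5.65, adjusted p = 7.96e-07). Hoxa10, a body axis gene, had no read in CM and was at least 266-fold higher in GHMT and at least 190-fold higher in AGHMT-labelled libraries. For each gene named here the groups did not overlap. After thinning Tnni3 (adjusted p = 0.0699) and Hoxa10 (0.0503) lost their calls between AGHMT-labelled libraries and CM in the quasi-likelihood test.

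The quasi-likelihood test called 3588 genes higher and 5233 lower in GHMT than in CM (40.7% higher; 30.5% with DESeq2's size factors in edgeR and 23.4% with limma on the deposited values). In AGHMT-labelled libraries it called 3576 higher and 3668 lower (49.4% higher; 28.7% with DESeq2's size factors in edgeR, 27.6% with DESeq2, 33.5% with limma and 37.3% after the GC correction). Lower calls of the latter were 2389 without AGHMT 1 and 2152 without AGHMT 3. At a mean log2 CPM up to 2, 17.4% of the calls were higher in GHMT and 28.2% in AGHMT-labelled libraries, but above 5 these shares were 81.4% and 86.7%. Groups did not overlap for 58.6% and 70.5% of genes, where chance gives 10%. Oxidative phosphorylation genes were lower in 77 of 78 cases in GHMT (camera adjusted p = 3.19e-11, 0.132 with an estimated correlation) and 75 of 78 in AGHMT-labelled libraries (1.16e-20 and 0.0524), and fatty acid oxidation genes in 30 (7.09e-07 and 0.127) and 29 (4.25e-10 and 0.0335) of 31. Sarcomere genes were lower in 27 of 28 cases in GHMT, with Ldb3 higher (7.09e-07 and 0.137), and in 25 of 28 in AGHMT-labelled libraries (26 adjusted over the list alone, 1.75e-12 and 0.056). Fibroblast and matrix genes were higher in 24 of 37 cases in GHMT (25 adjusted over the list alone, 3.03e-08 and 0.127) and in 25 (27 adjusted over the list alone, 2.72e-08 and 0.0599) in AGHMT-labelled libraries. With an estimated correlation 0 of 10 lists held in GHMT against CM by camera (adjusted p = 0.127 to 0.137). In AGHMT-labelled libraries 3 of 16 did, namely calcium handling and channels (0.039), fatty acid oxidation (0.0335) and the tricarboxylic acid cycle (0.0335).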

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

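The GC correction, the thinning, the removal of 3 libraries together and the counts recovered from the normalized values were chosen after the data were seen, and the other alternatives before. AGHMT here names the label. The 12 counts of genes stayed within 1.5 times their values under the stricter filter, no filter and the recovered counts, as did the 9 axis differences and shares within their spread under a 4-fold axis and the 3 axis differences without mitochondrial and oxidative phosphorylation genes. All 21 held so with GHMT 1, E 1 and CM 3 left out together. Where a value moved under another setting, the cause was not tested unless named. Named log2 fold changes that passed at either setting kept their direction except 4 given below, and some that passed at neither changed sign, such as Akt1 in AGHMT against GHMT, 0.34 and -0.36 after the GC correction. With DESeq2's size factors in edgeR, AGHMT against CM had 2216 genes higher and 5507 lower, the axis difference was 0.224, and 10.6% of genes lower in CM were lower in AGHMT than in GHMT. With total counts, AGHMT against GHMT had 142 lower, GHMT against E 1110 higher and 8111 lower, AGHMT against E 1622 higher, and CM against E 1767 higher and 6009 lower. Klf6 in GHMT against E went from 1.43 to -0.06. Without mitochondrially encoded genes AGHMT against GHMT had 3188 higher and 337 lower. DESeq2 gave 1642 lower in AGHMT against GHMT, 4580 higher in CM against E, 6676 lower in AGHMT against CM and a share of 14.4% for genes lower in CM between the sorted groups. Limma on the deposited values gave 3716 higher in AGHMT against GHMT, 2071 higher in AGHMT against E, 2092 lower in CM against E, 2207 higher in GHMT against CM and 1891 higher in AGHMT against CM, and the axis difference on these values was 0.195. With only the 2 groups compared, AGHMT against GHMT had 1074 higher and GHMT against CM 1889 higher and 3091 lower. The replicate block gave 1049 higher and 306 lower in AGHMT against GHMT and a share of 3.6% for genes lower in CM. Same-numbered deviations from group means correlated at -0.719 to 0.13 and 1 of 12 libraries matched its own number best. That check showed no pairing by number but cannot exclude a shared batch or sort. Between libraries of different numbers the correlations ran from -0.759 (CM 2 with E 1) to 0.789 (CM 3 with E 1), and CM 2 with E 3 gave 0.769. Some E and CM libraries thus shared deviations across numbers, and their cause was not tested. GlmTreat gave 330 lower in AGHMT against GHMT. A prior count of 0.5 gave axis differences of 0.195 for all genes and 0.599 for genes higher in CM.

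Fry called these lists higher in AGHMT than in GHMT where camera put them on the lower side, which follows from its not comparing them with other genes: other cardiac transcription factors (2.04e-04), atrial (1.53e-04), fetal (0.0305), FoxO (0.022), sterol (0.0277), amino acid (0.0371), endoplasmic reticulum stress (4.83e-04) and immediate early genes (0.00945). In that comparison fry also called 17 other lists that camera did not pass, on the same side as camera. In GHMT against CM it called other cardiac transcription factors (8.05e-04), atrial (7.95e-07), FoxO (0.00119) and inflammatory genes (0.0158) lower. After the GC correction AGHMT against GHMT had 1765 lower and GHMT against E 3117 lower, and in GHMT against E Tpm1 went from -0.47 to 0.61 and Atp5a1 from -1.36 to 0.46. The mitochondrially encoded list turned lower in GHMT against CM (0.0366) and the immediate early list higher in AGHMT against CM (0.883). The axis differences became 0.205, 0.345 for genes higher in CM and -0.158 for genes lower in CM, and the share of genes lower in CM was 14% between the sorted groups. Thinning leaves fewer reads, so counts fell, to 39 higher and 34 lower in AGHMT against GHMT, 776 and 362 in GHMT against E, 417 and 135 in AGHMT against E, 693 and 370 in CM against E, 868 and 915 in GHMT against CM, and 383 and 324 in AGHMT against CM. Cdk1 in AGHMT against GHMT went from 2.80 to -0.65. Axis differences after thinning were 0.154, 0.189 for genes higher in CM and 0.044 for genes lower in CM. As after the GC correction, the genes of these differences and of the shares were chosen again from the setting's own calls. Shares fell to 23.5% of genes lower in CM for GHMT against E, 38.4% of genes higher and 16.8% of genes lower in CM for AGHMT against E, and 5.4% and 3% between the sorted groups. Of named genes called at full depth, 13 of 46 kept their call after thinning in AGHMT against GHMT and 29 of 42 in GHMT against E. After the GC correction 46 of 48 and 40 of 45 did.

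Leaving out 1 library of the 2 groups compared gave 865 to 2903 higher and 91 to 1060 lower genes in AGHMT against GHMT, the ends being without AGHMT 2, AGHMT 3, AGHMT 3 and GHMT 3. It gave 1658 (E 1) to 3014 higher and 4215 to 5426 lower in GHMT against E, 2431 to 3281 higher and 1670 (AGHMT 3) to 4022 lower in AGHMT against E, and 2413 to 2906 higher and 2550 to 3485 lower in CM against E. It gave 3104 to 3644 higher and 4500 to 5212 lower in GHMT against CM, and 2807 to 3429 higher and 2152 (AGHMT 3) to 3828 lower in AGHMT against CM. Libraries of other groups enter the shared filter and fit, and leaving out 1 of them reached further: 3851 higher without E 1 in AGHMT against GHMT, 3141 higher without CM 3 and 5929 lower without AGHMT 3 in GHMT against E, 2664 higher without AGHMT 3 and 6283 lower without E 1 in GHMT against CM, and, without GHMT 3, 3862 higher and 4416 lower in AGHMT against E, 3500 and 4021 in CM against E, and 4128 and 4394 in AGHMT against CM. Axis differences ran from 0.154 to 0.191 for all genes, 0.447 to 0.559 for genes higher in CM and -0.402 (AGHMT 3) to -0.241 for genes lower in CM. For genes higher in CM the shares ran from 20.9% to 30.1% in GHMT against E, 50.9% to 59% in AGHMT against E and 14.5% (AGHMT 2) to 40.5% (E 1) between the sorted groups. For genes lower in CM they ran from 42.5% to 53.6%, 27.1% (AGHMT 3) to 48% and 0.8% (AGHMT 3) to 8.7%.

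A setting can also shift all genes together. Against TMM, the median log2 fold change in AGHMT against GHMT moved by -0.124 with DESeq2's size factors in edgeR, 0.52 with total counts, 0.366 without mitochondrially encoded genes, -0.144 with DESeq2 and -0.421 after the GC correction. In GHMT against E it moved by -0.213, -1.342, -0.189, -0.185 and 0.342 in the same order, in AGHMT against E by -0.339, -0.825, 0.176, -0.34 and 0.212, and in CM against E by 0.384, -1.009, 0.246, 0.388 and 0.451. In GHMT against CM the first 4 were -0.59, -0.336, -0.444 and -0.566. In AGHMT against CM it moved by -0.72 with the size factors, 0.186 with total counts, -0.724 with DESeq2 and -0.191 after the GC correction. Limma on the deposited values moved GHMT against E by -0.323, AGHMT against E by -0.313, CM against E by 0.374, GHMT against CM by -0.684 and AGHMT against CM by -0.677. Leaving out AGHMT 3 or E 1 moved AGHMT against GHMT by 0.625 and 0.594, GHMT against E by -0.504 and -0.488, GHMT against CM by -0.464 and -0.454, and AGHMT against CM by 0.177 and 0.153. The shallow GHMT libraries limit what can be read of low genes in each comparison that uses them. Their floor of 3 reads per library stood at 1.56 CPM in GHMT 2 and 3.93 CPM in GHMT 1.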

Other observations

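Every test of an explanation and every count of other splits in this part was chosen after the result it concerns was seen.

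Genes outside the comparisons above show other differences between the groups, tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment. In CM against E, 23 of 30 sterol and fatty acid synthesis genes were lower and Acss2 higher (24 and 1 adjusted over the list alone, camera adjusted p = 1.48e-08). Of 25 amino acid response and one-carbon genes 19 were lower in CM (21 adjusted over the list alone, 6.67e-07, adjusted p = 0.086 with an estimated correlation, range over alternatives 9.24e-09 to 0.086), led by the serine synthesis gene Psat1 at 2.84 ± 0.894 against 204 ± 30.5 CPM. In GHMT against E, 20 of these 25 genes were lower (0.00164, adjusted p = 0.434 with an estimated correlation, range over alternatives 7.35e-07 to 0.434), and Trib3, a stress-induced pseudokinase gene, had no read in GHMT and was at least 14-fold lower (adjusted p = 0.0042). The smooth muscle gene Cnn1 fell from 156 ± 32.7 CPM in E to 3.44 ± 1.68 in GHMT (-5.58, adjusted p = 3.1e-06), yet Mylk, Synpo2 and Itga8 were higher and 9 of 14 smooth muscle genes lower, and the list did not pass (0.556). FoxO targets rose above E in GHMT (13 higher of 30, with Igf1r, Gabarapl1, Eif4ebp1 and Klf2 lower, 2.5e-04, adjusted p = 0.0556 after thinning, range over camera's alternatives 9.85e-05 to 0.0556), and also in AGHMT-labelled libraries (13 higher and 4 lower, 0.00422, adjusted p = 0.0614 with an estimated correlation, range 0.00156 to 0.105) and in CM (15 higher and 4 lower, 0.00164). The transcription factor gene Foxo1 itself rose from 9.58 ± 0.588 to 41.5 ± 16.8 CPM (2.13, adjusted p = 5.18e-04), but not with total counts (0.82, adjusted p = 0.171) or after thinning (1.94, adjusted p = 0.199, range over alternatives 5.79e-14 to 0.199). No library of one group overlapped one of the other for the genes given with values here.

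Between the sorted groups, the pericyte gene Rgs5 stood at 279 ± 21.4 CPM in AGHMT-labelled against 17.0 ± 21.3 in GHMT libraries (log2 fold change 3.97, adjusted p = 0.00281 in the quasi-likelihood test). The alarmin gene Il33 stood at 96.9 ± 1.44 against 12.2 ± 5.11 CPM (2.94, 7.44e-04), the fatty acid binding gene Fabp4 at 45.8 ± 4.89 against 5.62 ± 2.30 (2.99, 8.45e-04), and the stearoyl desaturase gene Scd2 at 883 ± 55.1 against 360 ± 53.3 (1.29, 0.00478). The muscle ubiquitin ligase gene Trim63 (2.75, 0.00254) and the secreted chaperone gene Manf (3.39, 8.48e-04) were higher too. The groups did not overlap for these genes, and all 6 calls ended after thinning, where fewer reads were left and log2 fold changes were 3.84, 2.91, 2.95, 0.99, 3 and 3.82 in the order given. As lists, smooth muscle (5 higher, 1 lower of 14, 0.684), inflammatory (4 higher of 14, 6 adjusted over the list alone, 0.201), sterol (5 higher, 2 lower of 30, 0.201) and adipocyte genes (2 higher of 3, 0.193) did not pass camera. In CM, Hbb-bs, a beta globin gene whose paralogs share reads, had 17.9 ± 2.55 CPM and no read in E, at least 728-fold higher (adjusted p = 6.74e-06).

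A first pattern is that 74.3% of the calls between AGHMT-labelled and GHMT libraries were higher (95% interval 72.6 to 76). The intervals of such shares are binomial over called genes, treated as independent, and leave out the spread among libraries. With 1 library left out the share ran from 70.4% (CM 3) to 97% (AGHMT 3), beyond that interval. GC content bias cannot be told apart, since the share was 49.1% (47.4 to 50.7) after the GC correction, where the median of all genes moved by -0.421 and lower calls went from 689 to 1765, but 75.7% (74.2 to 77.1) with the median held. Mitochondrial transcripts taking most of the counts cannot be told apart either, since the share was 90.4% without them, where the median moved by 0.366, and 75.1% (73.4 to 76.7) with the median held. Holding the median fixes much of the share, so neither value decides, a rule set after both were seen, and depth stays open as well, with a median of 63.2% over 5 thinned draws (first 1 draw, 53.4%) and 95% intervals that include 50% in 3 draws and 74.3% in 4. An effect of the label stays open and untested.

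A second pattern is that Akt1 was not higher in the AGHMT-labelled than in the GHMT libraries. GC content bias was argued against as the whole cause, since its trend at the GC content of Akt1 (59.7%, against a median of 48.8%) lowers the gene by a log2 of -0.88 (SE 0.49) in AGHMT against GHMT, a rise and not a fall. The rule had asked for a fall of at least 3.46, the smallest log2 rise over E of another forced gene that passed. The rise that added Akt1 itself would give is not known. Vector reads left out of the gene's count cannot be told apart, since 3 of the 4 other forced genes passed as higher than E and Hand2 passed only under some alternatives. A vector with another species' or a recoded sequence could leave its reads uncounted, and the sequence of the vector is not used here. Wrong labels or a vector lost by 3 weeks also stay open and were not tested.

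A last pattern is that pooled reads of macrophage and endothelial genes were higher in AGHMT-labelled than in GHMT libraries, although the endothelial list did not pass camera (7 of 14 higher, 0.0948, and 0.5 with an estimated correlation, range over camera's alternatives 0.00165 to 0.5). Both groups were sorted on the reporter, which would remove cells without it. Flt1 did not pass the quasi-likelihood test (adjusted p = 0.655). After the GC correction it passed as lower in AGHMT-labelled libraries (log2 fold change -1.14, adjusted p = 0.0265, range over alternatives 0.0265 to 0.998). GC content was not tested as an explanation of this pattern. Pooled reads, scaled as CPM over non-mitochondrial reads, were 9.56 in GHMT, 218 in AGHMT-labelled, 449 in CM and 85.2 in E for 17 macrophage genes (highest Mrc1, 55.6 CPM), and 204, 359, 1600 and 79.4 for 14 endothelial genes (highest Flt1, 134 CPM). No gene was in another list, and 7 and 6 of them had at least 1 CPM in E and 17 and 14 in CM. By the rule set, depth was argued against, since the lowest AGHMT-labelled library stood at 8.37 and 1.33 times the highest GHMT library. The endothelial gap cannot be told apart from a shift of all genes together, whose median log2 fold change was 0.961 without mitochondrially encoded genes. Carry-over of cardiomyocyte RNA was argued against too, since the lower quartile of abundant cardiomyocyte transcripts was at 3.08% of CM (4.72% after the GC correction) against 54.4% for macrophage and 24.4% for endothelial genes. So were cells left from the fibroblast preparation at their share in E, where levels were 0.361 and 0.221 of those in AGHMT-labelled libraries. Such cells that passed the sort in a larger share than in E, and expression by the reprogrammed cells themselves, stay open and could not be tested, and the carry-over test first used the median gene (8.81%, and 9.89% after the GC correction).

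For each comparison the 6 libraries were split into 3 and 3 in all 10 ways and fitted on their own. As many genes came only from the real split, 1 of 10, in each of the 6 comparisons, with 1740 genes in AGHMT against GHMT, 6313 in GHMT against E, 9577 in AGHMT against E, 6961 in CM against E, 4980 in GHMT against CM and 9075 in AGHMT against CM. The highest other split gave 0 genes by edgeR's quasi-likelihood test in each, with up to 470, 350, 808, 1752, 75 and 354 genes at an unadjusted p under 0.05, and no other tool was run on them. For lists called by camera, the real split gave 7, 15, 21, 24, 11 and 14 lists and the highest other 1, 13, 22, 23, 12 and 15, with 1, 1, 3, 1, 2 and 4 splits giving as many. Each split other than the real one puts libraries of both groups on each side. A real difference between the groups then enters the spread within each side and lowers the number of genes called. The 0 genes of these splits are therefore no measure of chance for the real counts, and no conclusion is drawn from them. The lists called in these splits come from the same mixed groups. The splits are also too few for a share under 0.05.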
